A study of Mus musculus with 33 samples.

How the data were processed

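The deposited table gave FPKM per gene, with no read counts. Per the submitters' processing notes, polyA RNA reads were aligned to mm10 with TopHat2 and quantified with Cuffdiff, and the notes state no versions, annotation, strand setting or library normalization. Of 33 value columns, 32 were used. The column of Dppa2/4 day 11 Thy1+SSEA1- cells matched no sample, and the control sample of that day and gate is not analysed here, which left 4 pairs for Thy1-SSEA1+ against Thy1+SSEA1- and 8 libraries for change per day in Thy1+SSEA1- cells. A pair of columns that named arm and day 2 but no gate was assigned to the samples titled rtTA-MEF, since every other day 2 sample had a column of its own. Their titles give day 2 and their descriptions day 1 of OSKM-rtTA cells. The day 11 GFP+ control library has a description that names another gate, and its Nanog of 323 FPKM and Zfp42 of 126 FPKM were those of GFP+ cells. It was used as titled and left out in an alternative.

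The table held 37973 genes, of which 32914 had an Ensembl identifier in GENCODE vM21, 20213 of them protein coding, and 9407 were 0 in all libraries used. Genes were joined by identifier, and coordinates are GRCm38. Values were analysed as log2(FPKM + 1), and genes with FPKM of at least 1 in at least 2 libraries were tested. Comparisons were fitted with limma 3.58.1 (lmFit and eBayes with a trend, R 4.3.3), and p-values, two-sided, were adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. Dppa2/4 was compared with control with the stratum of day and gate as a block, gates with arm and day as a block, and change per day with the arm as a term. Whether the effect differed between strata was tested with the term of arm by late day, or arm by gate, beside the stratum block. Depth was implied from the low value at which FPKM times length piles up, read as 1 fragment, in 2001 single-transcript genes of over 2000 bp. Libraries correlated at 0.859 to 0.980.

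The pairing held in the values: the 2 libraries of a stratum deviated alike from the mean of their arm, with correlations of 0.21 to 0.76, and 10 of 13 libraries matched their own stratum best.

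The 19 gene lists were written from general knowledge before the data were examined, as were the comparisons, thresholds, naming rule and alternatives other than those named below as added. They cover core pluripotency, 2-cell-like, germline, fibroblast and mesenchymal, epithelial, cell cycle, p53 and senescence, DNA damage, chromatin modifier, lineage regulator, interferon, stress, immune, endothelial, keratinocyte, muscle, neural and glial, trophoblast and imprinted genes. Each symbol matched a gene of its own save 3 of 32 2-cell-like, 1 of 30 lineage and 1 of 16 immune symbols. The immune list holds both Adgre1 and Emr1, which name the same gene, so no immune gene was missing. Lists were tested with camera at a preset correlation of 0.01 and again at an estimated correlation, adjusted over lists. Counts within a list were taken from the adjustment over all genes and from one over the list alone. List scores, the mean difference over a list within a stratum, were tested two-sided by all sign flips over the 13 strata, adjusted by Benjamini-Hochberg over 19 lists. The 1 against 1 pair was read by a change of at least 4-fold at 5 FPKM or more, with percentiles among 10000 random lists drawn within 50 bins of expression.

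Genes named per comparison are up to 2 per list with the largest change past the threshold and the 5 highest and 5 lowest that moved the same way in at least 80% of strata or pairs with a mean FPKM of at least 1. Dppa2, Dppa4, Pou5f1, Sox2, Klf4, Myc, Thy1 and Fut9 are given for the main comparison whatever their result. A gene that this rule picked is not reported here. Other genes, among them Nanog and Esrrb by gate, Xist and H19 and the members behind small counts, were chosen after values were seen. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile normalization, no trend, no block, leaving out the day 11 GFP+ control library, each day or each stratum, pair or library, and for the main comparison adding the rtTA-MEF pair. Those without the library labelled Dppa2/4 day 4 Thy1+SSEA1-, with protein-coding genes alone and, for the gates and the change per day, without day 2 were chosen after the data were seen.

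The calls were tried on simulated values with 200 genes changed. A change of 1 on the log2 scale was recovered in 89% of them for Dppa2/4 against control, 39% for late against early days, 27% for SSEA1+ or GFP+ against other gates, 63% for Thy1-SSEA1- against Thy1+SSEA1-, 8% for Thy1-SSEA1+ against Thy1+SSEA1- and 54% for GFP+ against Thy1-SSEA1+. For change per day the smaller simulated change was recovered in 55% and 66%, and for OSKM against rtTA-MEF in 0%. False calls numbered 0 to 15. The simulated noise was drawn independently for each gene, while genes of many lists were correlated in the data. The simulation therefore gives no bound on false calls in the data. Signals of Pou5f1, Sox2, Klf4 and Myc join transgene and endogenous transcripts. Families with copies of like sequence, such as the Usp17 and ribosomal protein genes, share reads in ways the values do not resolve. Genes were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.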

Results

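RNA was sequenced from mouse embryonic fibroblasts that were being reprogrammed to pluripotency by doxycycline-induced OSKM (Pou5f1, also called Oct4, with Sox2, Klf4 and Myc). One arm also overexpressed Dppa2 and Dppa4, a pair of small DNA-binding proteins of pluripotent and germ cells, and the other carried a control. Cells were sorted on days 2, 4, 8, 11 and 14. The sort used Thy1, a fibroblast surface antigen that reprogramming cells lose, SSEA1, a carbohydrate antigen that they gain, and an Oct4-GFP reporter that turns on late. The labels list 33 samples, and 32 libraries had values: 13 control and 17 Dppa2/4 libraries of OSKM cells, and 2 day 2 libraries titled rtTA-MEF, 1 per arm. Each arm, day and gate held 1 library, so there were no replicates. In 13 combinations of day and gate, called strata here, both arms were present: Thy1+SSEA1- on days 2, 4, 8 and 14, Thy1-SSEA1- on days 2, 4, 8 and 11, Thy1-SSEA1+ on days 8, 11 and 14, and GFP+ on days 11 and 14. Depth per library, worked back from the values as stated under the processing, was 21.6 to 43.2 M fragments in OSKM cells, with a median of 31.3 in the control arm and 29.2 in the Dppa2/4 arm. The 2 rtTA-MEF libraries stood at 16.4 and 14.0 M.

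Control OSKM cells switched on their own Dppa2 and Dppa4 late and by gate. Control Dppa2 was 0.149 to 0.527 FPKM in the 4 Thy1+SSEA1- libraries and 0.256 to 0.916 in the 4 Thy1-SSEA1- libraries. It was 6.4 to 14.1 in the 3 Thy1-SSEA1+ libraries and 45.4 to 66.1 in the 2 GFP+ libraries. In the Dppa2/4 arm, Dppa2 was 81.8 to 182 FPKM in 5 Thy1-SSEA1- libraries, 43.2 to 123 in 3 Thy1-SSEA1+ libraries and 49.3 to 61.5 in 3 GFP+ libraries, so the arms overlapped in the GFP+ gate. Dppa4 followed the same order, with 7.23 to 28.6 FPKM in control Thy1-SSEA1+ cells and 85.0 to 91.1 in control GFP+ cells. The library labelled Dppa2/4 day 4 Thy1+SSEA1- stood apart from its arm, with 0.354 FPKM of Dppa2 and 0.409 of Dppa4. The other 3 Dppa2/4 libraries of its gate had 171, 175 and 599 FPKM of Dppa2. Totals of genes called in comparisons that use that library are given with and without it. Counts within gene lists are given with it alone. Its effect is part of every mean over the 13 strata below, and of every count of strata. A count of 13 of 13 thus includes a stratum whose library labelled Dppa2/4 had Dppa2 at control level.

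**Figure D1:**
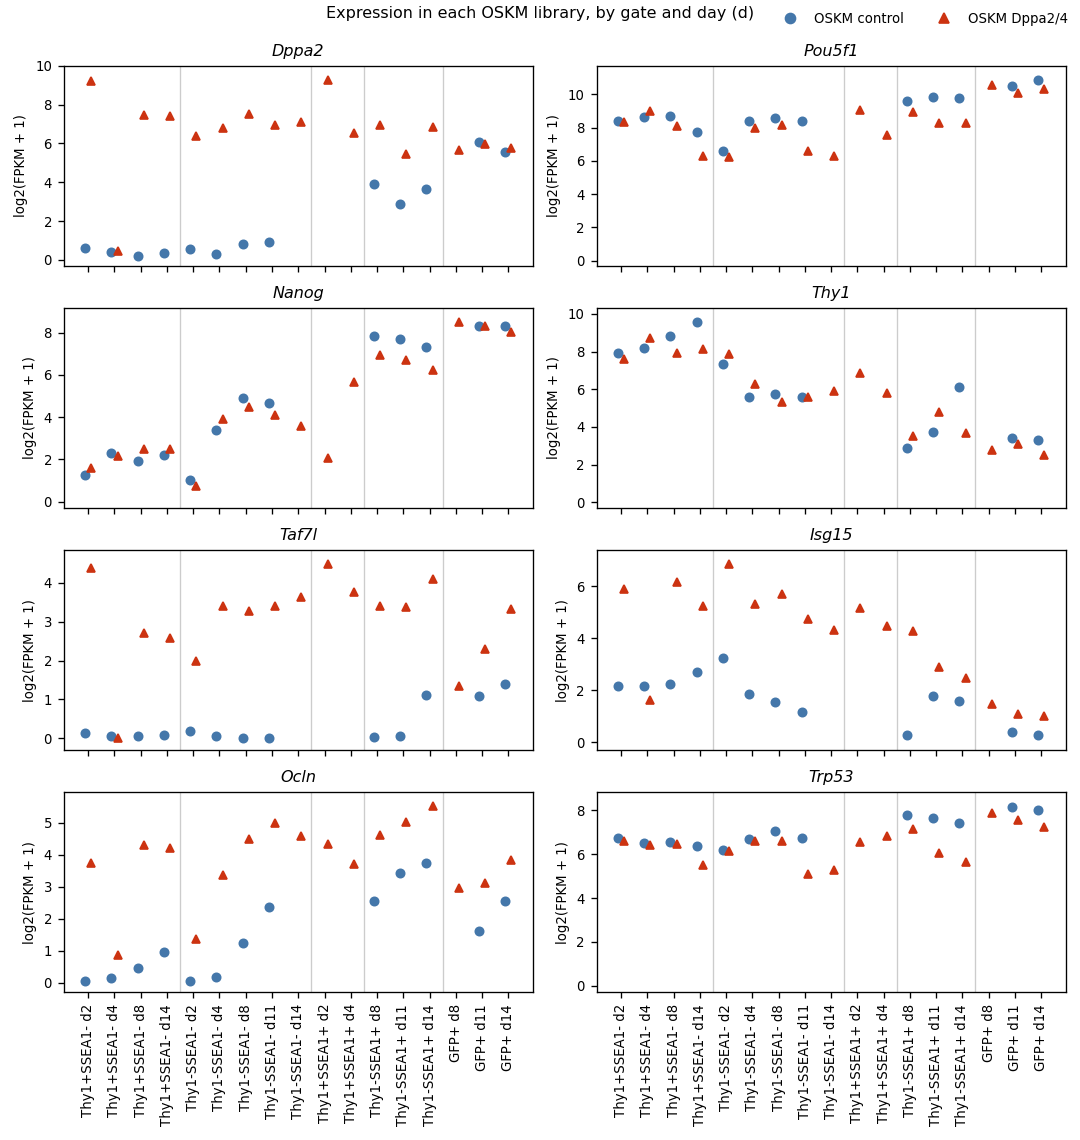
Expression, as log2(FPKM + 1), of Dppa2, Pou5f1, Nanog, Thy1, Taf7l, Isg15, Ocln and Trp53 in each OSKM library, by gate and day, with circles for control and triangles for Dppa2/4. Dppa2 lies near 0 in control cells outside the SSEA1+ and GFP+ gates, and in the library labelled Dppa2/4 day 4 Thy1+SSEA1-.

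The main comparison asked what added Dppa2/4 changed in OSKM cells of the same day and gate. The germline gene Taf7l, the interferon gene Isg15 and the epithelial gene Ocln rose with Dppa2/4, while Pou5f1 and Trp53 fell. Dppa2 (ENSMUSG00000072419, GRCm38 chromosome 16, 48303908 to 48319723) was higher by 4.38 on the log2 scale (SE 0.77, n = 13 strata, limma adjusted p = 0.00175), with a mean of 141 against 11.3 FPKM. Its neighbour Dppa4 (ENSMUSG00000058550, chromosome 16, 48283733 to 48294237) was higher by 4.44 (SE 0.78, adjusted p = 0.00178), with 176 against 17.3 FPKM. After them, Taf7l rose most among genes of at least 1 FPKM that moved the same way in at least 80% of the strata. Next came Trf, the iron carrier transferrin, by 2.57 (SE 0.32, adjusted p = 0.000426, higher in 13 of 13 strata), and Rasd2, a Ras-like GTPase, by 2.56 (SE 0.36, adjusted p = 0.000729). The lowest were Bcl11a, a zinc finger transcription factor, at -1.73 (SE 0.30, adjusted p = 0.00163), Clec3b, which encodes tetranectin, at -1.65, Fndc3c1 at -1.51, Rragb, a GTPase of amino acid sensing, at -1.48, and Sostdc1, a secreted antagonist of BMP and Wnt, at -1.48, each lower in 11 or 12 strata.

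Of 28 germline genes measured, 16 rose and 0 fell with Dppa2/4, and 20 rose when adjusted over the list alone (camera adjusted p = 5.1e-08, and adjusted p = 0.25 with an estimated correlation). Taf7l, the testis form of a subunit of the basal factor TFIID (ENSMUSG00000009596, chromosome X, 134460118 to 134476490), rose by 2.62 (SE 0.29, adjusted p = 0.000291, 12 of 13 strata), from 0.339 to 8.43 FPKM. Ddx4, the germ cell RNA helicase (chromosome 13, 112598333 to 112652475), rose by 2.50 (SE 0.29, adjusted p = 0.000291), from 0.681 to 9.55 FPKM. Among 9 measured 2-cell-like genes, which mark the earliest embryonic cleavage stages and a rare state of embryonic stem cells, 8 rose and 0 fell, and 9 rose when adjusted over the list alone (camera adjusted p = 0.00029, and adjusted p = 0.69 with an estimated correlation). Their levels were low. Dub3, a deubiquitinase of the Usp17 family whose copies share sequence, rose by 0.89 (SE 0.18, adjusted p = 0.00339), at 1.19 against 0.0378 FPKM, and Tdpoz4 by 0.74 (SE 0.14, adjusted p = 0.00271). After quantile normalization, 4 of the 2-cell-like genes passed.

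Of 19 interferon response genes measured, 16 rose and 0 fell, and the same numbers passed when adjusted over the list alone (camera adjusted p = 5.1e-08, and adjusted p = 0.66 with an estimated correlation). Isg15, a ubiquitin-like modifier induced by interferon (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), rose by 2.45 (SE 0.41, adjusted p = 0.00147, 12 of 13 strata), from 2.73 to 32.8 FPKM. Irf7, a master regulator of type I interferon genes (chromosome 7, 141262706 to 141266481), rose by 2.31 (SE 0.33, adjusted p = 0.000827, 13 of 13 strata), from 1.76 to 17.1 FPKM. Of 9 measured immune cell markers, Cd68 at 0.54 (SE 0.18, adjusted p = 0.039) and Cd14 at 0.50 (SE 0.11, adjusted p = 0.00758), genes of macrophages, rose and the other 7 did not pass, whether adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.82).

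Of 26 epithelial genes measured, 12 rose and 0 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.003, and adjusted p = 0.8 with an estimated correlation). Ocln, the tight junction protein occludin (ENSMUSG00000021638, chromosome 13, 100496507 to 100552718), rose by 2.32 (SE 0.27, adjusted p = 0.000291, 13 of 13 strata), from 3.13 to 17.9 FPKM. Pkp3, a plakophilin of desmosomes, rose by 2.10 (SE 0.35, adjusted p = 0.00138, 13 of 13 strata), from 10.1 to 43.6 FPKM. Among the 33 fibroblast and mesenchymal genes, Lum, a collagen-binding proteoglycan, at -1.15 (SE 0.30, adjusted p = 0.0145), Col1a1, the main collagen of fibroblasts, at -0.79 (SE 0.24, adjusted p = 0.0304), and Pdgfra fell, while Cd44, Twist2 and Cdh2 rose, and the same counts of 3 and 3 held adjusted over the list alone (camera adjusted p = 0.27). The fibroblast list had a median of -0.09, which was 0.03 without day 2.

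Core pluripotency genes split. Of 31 measured, Tex19.1, a gene of germ and pluripotent cells, rose by 2.38 (SE 0.41, adjusted p = 0.0016), Lefty1 by 1.53 (SE 0.32, adjusted p = 0.00424) and Lefty2 by 1.48 (SE 0.31), the last 2 being secreted antagonists of Nodal. Tfcp2l1, Fbxo15, Trim28 and Mybl2 fell, by between -0.56 and -0.91, and 24 genes did not pass. Adjusted over the list alone, 3 rose and 3 fell, and camera placed the list lower (adjusted p = 0.044, and adjusted p = 0.8 with an estimated correlation). Of the OSKM factors, whose signal adds the transgene to the cell's own gene, Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772) fell by 0.72 (SE 0.17, adjusted p = 0.00806, lower in 12 of 13 strata), from 644 to 411 FPKM. Myc fell by 0.58 (SE 0.20, adjusted p = 0.0456) and Klf4 by 0.50 (SE 0.17, adjusted p = 0.0483), and Sox2 stood at -0.61 (SE 0.23, adjusted p = 0.0661). Fut9, the fucosyltransferase that makes the SSEA1 antigen, rose by 0.44 (SE 0.12, adjusted p = 0.0171), a call that was lost after quantile normalization. Thy1 stood at -0.24 (SE 0.25, adjusted p = 0.51).

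Trp53, which encodes p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), fell by 0.69 (SE 0.16, adjusted p = 0.00906, lower in 13 of 13 strata), from 149 to 92.8 FPKM. Of the 20 genes of the p53 and senescence list, Bbc3, Bax, Sesn1, Sesn2 and Phlda3 also fell, by between -0.35 and -0.52, while the cell cycle inhibitors Cdkn2b, by 0.59 (SE 0.19, adjusted p = 0.0357), and Cdkn1a, by 0.38, rose. Adjusted over the list alone, 4 rose and 7 fell (camera adjusted p = 0.34). Among 28 cell cycle genes, Mcm5 (-0.62, SE 0.22, adjusted p = 0.0494), Mcm3 (-0.57, SE 0.19, adjusted p = 0.044) and Mcm7, subunits of the replicative helicase, and Tyms, thymidylate synthase, fell. None of the 28 passed adjusted over the list alone or after quantile normalization (camera adjusted p = 0.0049, and adjusted p = 0.8 with an estimated correlation). Of 24 DNA damage genes, Xrcc5, the Ku80 subunit of end joining, fell by 0.67 (SE 0.12, adjusted p = 0.00208), as did H2afx, by 0.63 (SE 0.18, adjusted p = 0.0206), and Parp1, while Lig4 and Atr rose. The counts of 2 and 3 were the same adjusted over the list alone (camera adjusted p = 0.044, and adjusted p = 0.8 with an estimated correlation). Of 36 chromatin modifiers, Chaf1b (-0.57, SE 0.18, adjusted p = 0.0325), Wdr5 (-0.41, SE 0.10, adjusted p = 0.00799) and Setdb1 fell and Setdb2 rose. Wdr5 alone of these was left adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.8 with an estimated correlation).

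Markers of other cell types moved in single genes. Of 7 endothelial genes, the junction proteins Cldn5, by 1.85 (SE 0.34, adjusted p = 0.00223), and Esam, by 1.25 (SE 0.24, adjusted p = 0.00255), rose together with Egfl7, and Tek, the angiopoietin receptor, fell, with counts of 3 and 1 adjusted over the list alone. The endothelial median was -0.01 beside a mean of 0.44 (camera adjusted p = 0.63). Of 15 lineage regulators, Hand1, a factor of heart and trophoblast, rose by 1.81 (SE 0.31, adjusted p = 0.00155), as did Gata2 by 0.71 (SE 0.18, adjusted p = 0.0106), Gata4, Nes and Nkx2-5. Adjusted over the list alone, 5 rose and 1 fell, and the list had a median of -0.03 beside a mean of 0.19 (camera adjusted p = 0.75). The trophoblast list of 7 had Krt7, by 1.99 (SE 0.36, adjusted p = 0.0021), and Hand1 higher and Tfap2c lower, with the same 2 and 1 adjusted over the list alone, a median of -0.04 and a mean of 0.40 (camera adjusted p = 0.75). Des, the muscle filament desmin, rose by 1.38 (SE 0.33, adjusted p = 0.00888) among 4 muscle genes. In the neural and glial list of 10, Gfap, an astrocyte filament, rose by 1.32 (SE 0.26, adjusted p = 0.00345). Of 18 stress genes, Ier3, by 0.98 (SE 0.25, adjusted p = 0.0139), and the heat shock genes Hspa1b, by 0.62 (SE 0.13, adjusted p = 0.00374), and Hspa1a rose. Each of these last 3 lists kept the same counts adjusted over the list alone, with camera adjusted p = 0.6, 0.33 and 0.75, and the stress median of 0.05 was -0.01 after quantile normalization. No gene of the 11 keratinocyte and 8 imprinted genes measured passed, over all genes or adjusted over the list alone (camera adjusted p = 0.75 and 0.51). The keratinocyte median and test pointed down and its mean was 0.02.

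In all, 2629 of 16835 genes tested were higher and 1304 lower with Dppa2/4, of which 392 and 51 changed at least 2-fold (limma, Benjamini-Hochberg adjusted over all genes). Because each stratum held 1 library per arm, these p-values measure how alike the arms differed over days and gates, not over independent transductions. After quantile normalization the counts were 1971 and 2107, and without the stratum block they were 719 and 86. Without day 8 they were 1516 and 662, without day 11 they were 1561 and 547, without day 14 they were 1808 and 482, and without the day 11 Thy1-SSEA1- stratum 852 were lower. With a mean of at least 5 FPKM required, 1257 were higher. Pou5f1 stood at -0.59 and did not pass without day 14, and Trp53 did not pass without day 14 (-0.54) or day 11 (-0.51). The calls of Myc, Klf4, Mcm3, Mcm5, Cdkn2b, Chaf1b, Cd68 and Col1a1 were each lost when 1 or more single strata were left out. Folds on log2(FPKM + 1) understate the change of genes below a few FPKM.

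**Figure D2:**
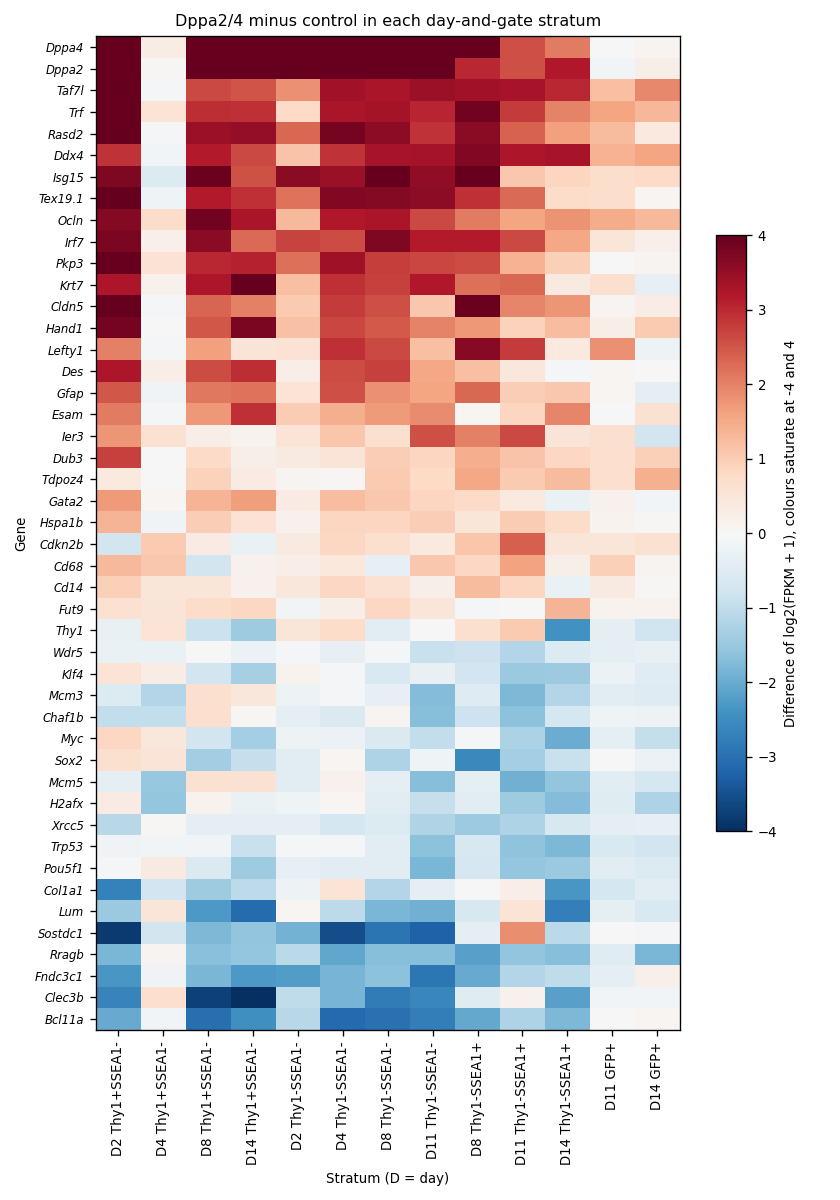
Difference in log2(FPKM + 1), Dppa2/4 minus control, of the named genes in each of the 13 strata, with colours saturating at -4 and 4. Ocln is higher in the library labelled Dppa2/4 in 13 of 13 strata, and Taf7l and Isg15 in 12, all but day 4 Thy1+SSEA1-.

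Scored as whole lists per stratum, interferon response genes were higher by a mean of 1.01 (SE 0.18, n = 13 strata), germline genes by 0.66 (SE 0.08) and 2-cell-like genes by 0.55 (SE 0.12), each higher in 13 of 13 strata. Their sign-flip permutation p was 0.000244, the smallest that flipping 13 strata allows, and 0.0015 after Benjamini-Hochberg adjustment over 19 lists. The flips treat strata as independent, though gates of the same day are among them and the labels give no independent transductions. The permutation p-values can therefore be too small as evidence over independent cultures. In the day 4 Thy1+SSEA1- stratum the interferon, germline and 2-cell-like scores were close to 0, at 0.025, 0.031 and 0.033. Without that stratum they were higher by 1.09, 0.71 and 0.59, each in 12 of 12 strata (adjusted permutation p = 0.0031). The interferon score was also small in the GFP+ gate, at 0.077 on day 11 and 0.108 on day 14, where Dppa2 overlapped between the arms. Epithelial genes were higher by 0.68 (SE 0.18, adjusted permutation p = 0.0083, 11 of 13 strata), endothelial genes by 0.44 (SE 0.11, adjusted permutation p = 0.0081, 12 of 13) and lineage regulators by 0.19 (SE 0.07, adjusted permutation p = 0.047, 10 of 13). The endothelial and lineage calls were lost after quantile normalization, and the lineage call was also lost when any of several single strata was left out. The core pluripotency score averaged -0.09 (SE 0.16, adjusted permutation p = 0.72) and had opposite signs by gate: 0.56, 0.39 and 0.23 in Thy1+SSEA1- cells on days 2, 8 and 14, against -1.26, -0.69 and -0.89 in Thy1-SSEA1+ cells on days 8, 11 and 14. The day 4 Thy1+SSEA1- stratum, whose library labelled Dppa2/4 had Dppa2 at control level, had 0.52, about as much as day 2. The list mean of that library was 2.11, and control libraries of the gate went from 1.42 on day 2 to 2.04 on day 14. That library may hold control cells, as the closing part describes. Its stratum therefore cannot decide whether the positive sign in that gate goes with Dppa2/4. In Thy1-SSEA1+ cells, Nanog, a core pluripotency factor, was 201 ± 36.4 FPKM (SD over 3 days) in control and 100 ± 24.6 with Dppa2/4, and Esrrb, another, 74.1 ± 10.2 and 18.8 ± 5.87. In GFP+ cells Nanog was 320 ± 4.46 (2 days) in control and 315 ± 50.8 (3 days) with Dppa2/4, and Esrrb 198 ± 0.766 and 132 ± 17. Trophoblast (0.40, adjusted permutation p = 0.074) and muscle (0.42, 0.078) scores did not pass. The remaining scores lay between -0.20 for the cell cycle and 0.11 for stress genes, with adjusted permutation p from 0.26 to 0.9. The day 4 Thy1+SSEA1- stratum had a cell cycle score of -1.25. Without it the cell cycle score was -0.11, and the immune score went from -0.02 to -0.12 (adjusted permutation p = 0.57 for each).

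**Figure D3:**
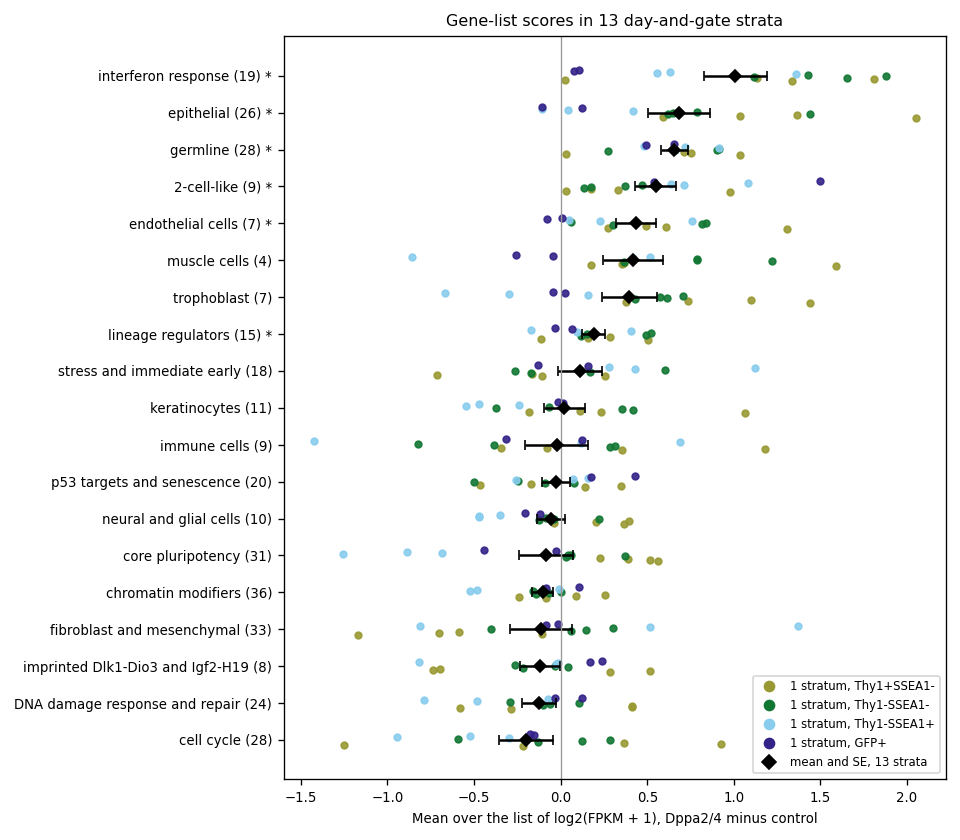
Mean difference in log2(FPKM + 1) over each of 19 gene lists, Dppa2/4 minus control, in each of 13 strata (dots, coloured by gate), with the mean and its standard error (diamonds) and the number of genes in brackets. Interferon, germline and 2-cell-like scores are above 0 in all 13 strata, though close to 0 in day 4 Thy1+SSEA1-. The interferon score is 0.077 and 0.108 in the GFP+ strata of days 11 and 14.

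The effect of Dppa2/4 on days 8 to 14 (9 strata) was set against that on days 2 and 4 (4 strata). The early strata were all of SSEA1- gates, and the Thy1-SSEA1+ and GFP+ strata were all late. A difference in this contrast can therefore come from time or from gate. Crabp2, a carrier of retinoic acid, had an effect higher by 1.70 in the later strata (SE 0.23, adjusted p = 0.023), Neil3, a DNA glycosylase, by 1.33 (SE 0.16, adjusted p = 0.0107) and Dzip3, a ubiquitin ligase, by 0.99 (SE 0.12, adjusted p = 0.0107). Agpat2, an acyltransferase of lipid synthesis, had an effect lower by -1.18 (SE 0.17, adjusted p = 0.0275). No member of any list passed over all genes. The effect on core pluripotency genes was lower in the late strata by a median of -0.79 (camera adjusted p = 0.00023, and adjusted p = 0.47 with an estimated correlation), with 0 of 31 past adjusted over the list alone. In SSEA1- gates the score difference of this list was 0.033 to 0.563 early and 0.042 to 0.388 late. The negative values, -1.256 to -0.027, lay in the Thy1-SSEA1+ and GFP+ strata, which have no early counterpart. The effect on epithelial genes was lower in the late strata by a median of -0.57 (camera adjusted p = 0.0003, and adjusted p = 0.47 with an estimated correlation), with 3 of 26 adjusted over the list alone. In SSEA1- gates the epithelial score difference was 0.588 to 2.049 early and 0.648 to 1.365 late, against -0.11 to 0.42 in the Thy1-SSEA1+ and GFP+ strata. Immune (2 of 9 adjusted over the list alone) and keratinocyte genes (3 of 11) were lower and germline, cell cycle, DNA damage, 2-cell-like and fibroblast genes higher by camera (adjusted p from 0.0063 to 0.037), and none of these held with an estimated correlation (adjusted p of at least 0.47). These 4 genes were the calls among 16835 tested, with 3213 at an unadjusted p under 0.05. Without the library labelled Dppa2/4 day 4 Thy1+SSEA1-, limma called 0, and the cell cycle median turned from 0.21 to -0.03. Neil3 and Dzip3 were the calls left without the day 11 GFP+ control library, and limma called 0 without the stratum block, with 692 at an unadjusted p under 0.05.

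Whether the effect differed between cells that had reached SSEA1 or GFP and cells that had not was asked on days 8 to 14, with 5 strata against 4. The overexpressed pair differed most: the effect on Dppa4 was lower by -5.11 (SE 0.79, adjusted p = 0.037) and on Dppa2 by -4.97 (SE 0.73, adjusted p = 0.0349) in the SSEA1+ or GFP+ strata, where control cells made both. The effects on Apoc1, an apolipoprotein (-3.41, SE 0.53, adjusted p = 0.037), Ly6g6c (-2.68), Amt, an enzyme of glycine cleavage (-2.44), and Stmn2 and Tubb3, proteins of neuronal microtubules (-2.24 and -2.09), were lower too. So were those on Des (-2.13), the junction genes Cldn6 (-2.03, SE 0.28, adjusted p = 0.027) and Ocln (-1.61, SE 0.26, adjusted p = 0.042), and Eras, a Ras of embryonic stem cells (-1.39, SE 0.21, adjusted p = 0.037). Higher in those strata were the effects on Wnt16 (2.54, SE 0.39, adjusted p = 0.037), Abat, which degrades GABA (2.48), Gdpd2 (2.42), Fbxo32, a ubiquitin ligase subunit (2.11), Igfbp3, which binds insulin-like growth factors (1.90), and Btg2, a p53 target (1.23, SE 0.15, adjusted p = 0.024). Of 26 epithelial genes, Cldn6 and Ocln passed over all genes and 16 adjusted over the list alone, all lower (camera adjusted p = 5.9e-12, and adjusted p = 0.12 with an estimated correlation). Of 19 interferon genes, 9 were lower adjusted over the list alone (camera adjusted p = 3.7e-10, and adjusted p = 0.21 with an estimated correlation). Eras and 4 other core pluripotency genes were lower adjusted over the list alone (camera adjusted p = 8.9e-10, and adjusted p = 0.2 with an estimated correlation). Cell cycle, DNA damage, chromatin and trophoblast genes were lower and p53, 2-cell-like, fibroblast and stress genes higher by camera (adjusted p from 8.9e-10 to 0.022), and none held with an estimated correlation (adjusted p from 0.12 to 0.53). Adjusted over the list alone, 4 of 7 trophoblast genes were lower, and 2 of 20 p53 genes and 4 of 18 stress genes higher. In all, 36 genes had a higher and 33 a lower effect, of 16335 tested. Stmn2 was the call left without the day 11 GFP+ control library, limma called 0 without the stratum block (795 at an unadjusted p under 0.05) and 263 among protein-coding genes alone. The counts were 140 with a pseudocount of 0.1, 44 with a mean of at least 5 FPKM and 13 without a filter on low values.

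Gates were compared within arm and day, for what goes with losing Thy1, gaining SSEA1 and activating the Oct4 reporter. Thy1-SSEA1- cells differed from Thy1+SSEA1- cells in few genes that passed over 7 pairs. Gzme, a granzyme, was higher by 3.43 (SE 0.35, adjusted p = 0.0406, 7 of 7 pairs), at 55.7 against 4.55 FPKM, as was Rps2-ps13, a ribosomal protein pseudogene, by 3.11 (SE 0.34, adjusted p = 0.0499). Defb1, an antimicrobial peptide, was lower by -2.39 (SE 0.23, adjusted p = 0.0402), and Epas1, a hypoxia-inducible factor, by -1.49 (SE 0.12, adjusted p = 0.0185, lower in 7 of 7 pairs). No list member passed over all genes, and adjusted over the list alone 5 of 8 imprinted genes were higher and 2 of 5 endothelial genes lower. Camera placed fibroblast (adjusted p = 5.5e-05), imprinted (6.6e-05) and core pluripotency genes (0.0017) higher, each with an adjusted p = 0.98 with an estimated correlation. Without day 2, whose Thy1-SSEA1- libraries are described in the closing part, the fibroblast median went from 0.60 to -0.15 and limma called 82 genes in place of 4. The 4 calls, among 15473 genes with 1611 at an unadjusted p under 0.05, were 0 without a filter on low values (2270 at an unadjusted p under 0.05), 0 without any 1 of the 3 control pairs or the day 8 or 14 Dppa2/4 pair, and 7 without the day 2 Dppa2/4 pair. Defb1 was the call left without the library labelled Dppa2/4 day 4 Thy1+SSEA1-.

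Thy1-SSEA1+ cells carried more Tdgf1, Nanog and Epcam RNA, and less Col1a1 RNA, than Thy1+SSEA1- cells of the same arm and day (n = 4 pairs). Tdgf1, a Nodal coreceptor, was higher by 5.42 (SE 0.43, adjusted p = 0.00995), at 239 against 4.68 FPKM, and Nanog by 4.83 (SE 0.37, adjusted p = 0.0091), at 148 against 3.9. Trh, a hormone precursor, was higher by 4.98 (SE 0.46, adjusted p = 0.0101), and the embryonic stem cell microRNA gene Mir293 stood at 592 FPKM and was listed at 0 in Thy1+SSEA1- cells. Epcam, an epithelial adhesion molecule, was higher by 3.84 (SE 0.42, adjusted p = 0.0101), Tfap2c by 3.59 (SE 0.25, adjusted p = 0.0091) and Dnmt3l, a cofactor of DNA methylation, by 3.12 (SE 0.68, adjusted p = 0.0258). Prelp, a matrix proteoglycan, was lower by -4.51 (SE 0.42, adjusted p = 0.0101), Col1a1 by -3.80 (SE 0.48, adjusted p = 0.011), at 36.8 against 420 FPKM, and Isg15 by -1.92 (SE 0.29, adjusted p = 0.0138). Thy1, the sorted antigen, was lower by -4.57.

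In that comparison 29 of 31 core pluripotency genes were higher (30 adjusted over the list alone), as were 25 of 28 cell cycle genes (26), 20 of 26 epithelial (22), 20 of 36 chromatin (26) and 14 of 24 DNA damage genes (19). Of 33 fibroblast genes 31 were lower (33 adjusted over the list alone), and of 19 interferon genes 7 (12). Camera adjusted p ran from 2.7e-17 for pluripotency to 0.00043 for interferon genes, and with an estimated correlation the adjusted p was 0.39 or 0.44. Bub1, a spindle checkpoint kinase (2.22), and Chek1, a DNA damage kinase (2.17), led their lists. Of 22 germline genes, Piwil2, Tdrd12, Rhox9 and Rhox6 were higher (2 adjusted over the list alone, camera adjusted p = 0.00036, and adjusted p = 0.49 with an estimated correlation). Keratinocyte genes were higher in 6 of 11, Sfn and Krt17 most (7 higher and 1 lower adjusted over the list alone). Tfap2c, Rhox6, Elf5 and Tead4 of 6 trophoblast genes, and Olig1 and Olig2 of 10 neural genes, were higher. Dusp1, Junb, Ier3 and Egr1 of 18 stress genes were lower, and these 3 lists had the same counts adjusted over the list alone. Camera called these last 4 lists (adjusted p = 0.0021, 0.0057, 0.032 and 0.039), none with an estimated correlation (adjusted p from 0.39 to 0.67). Of 12 lineage regulators, Otx2 and Eomes were higher and Tbx15, Msx1, Lhx9 and Nes lower (2 and 5 adjusted over the list alone). Of 20 p53 and senescence genes, Pmaip1 (1.56), Perp and Trp53 were higher and Cdkn2b (-1.82), Cdkn2a, Phlda3 and Cdkn1a lower, with the same counts adjusted over the list alone, a median above 0 and a mean of -0.02. Camera adjusted p for these 2 lists was 0.39 and 0.76. In all, 1607 genes were higher and 2049 lower of 15196. After quantile normalization 2088 were higher and 2043 lower, so the excess of lower genes was lost. The total of 3656 was 1793 without the pair block and 1006 to 3365 with 1 pair left out: 1006 without the day 14 control pair, 1107 without the day 8 control pair and 2316 without the day 14 Dppa2/4 pair. Without a filter on low values limma called 0, with 7430 at an unadjusted p under 0.05.

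GFP+ cells were compared with Thy1-SSEA1+ cells, which had not turned the reporter on (n = 5 pairs). Dppa5a, an RNA-binding protein of pluripotent cells, was higher by 3.57 (SE 0.69, adjusted p = 0.00814, 5 of 5 pairs), at 2420 against 407 FPKM. Dnmt3l was higher by 3.33 (SE 0.57, adjusted p = 0.00526), Zfp42, also called Rex1, a marker of naive cells, by 3.28 (SE 0.45, adjusted p = 0.00268) and Tdrd12, a tudor protein of the germline, by 2.65 (SE 0.28, adjusted p = 0.00148). Aldh3a1, an aldehyde dehydrogenase, was lower by -3.97 (SE 0.24, adjusted p = 0.00071), at 11.6 against 189 FPKM. Keratin gene Krt19 was lower by -3.69 (SE 0.28, adjusted p = 0.000913), and Dlk1, an imprinted Notch ligand, by -3.68 (SE 0.11, adjusted p = 0.000274), at 1.90 against 36.5 FPKM. Vim, the mesenchymal filament vimentin, was lower by -2.64 (SE 0.26, adjusted p = 0.00124), at 192 against 1310 FPKM, and Isg15 by -1.76 (SE 0.24, adjusted p = 0.00272). Short RNAs, whose FPKM is unstable, were also among the extremes: Mir135a-1, SNORD59 and Snord45c higher, and AL954388.1 and AC134908.1 listed at 0 in GFP+ cells.

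Of 31 core pluripotency genes, 28 were higher in GFP+ cells and Lefty1 was lower (29 and 1 adjusted over the list alone). Cell cycle genes were higher in 19 of 28 (22 adjusted over the list alone), DNA damage genes in 18 of 24 (20) and germline genes in 14 of 27 (14), and chromatin genes were higher in 22 and lower in 5 of 36 (23 and 5), with Tet3, Mll1, Kdm6b, H3f3a and H3f3b lower. Fibroblast genes were lower in 31 of 33 (31 adjusted over the list alone), keratinocyte genes in 8 of 8 (8) and imprinted genes in 7 of 7 (7). Epithelial genes were lower in 14 of 26, with Tjp3 higher (15 and 1 adjusted over the list alone), and interferon genes were lower in 8 of 14, with Stat2 higher (8 and 1). Stress genes were lower in 10 of 18, with Atf4 higher (10 and 1). Camera adjusted p over these 11 lists ran from 4.2e-12 for pluripotency to 0.026 for stress genes, and with an estimated correlation the adjusted p was 0.46 or 0.69. The endothelial median was -0.51 beside a mean of -0.01, with Pecam1, Vwf and Egfl7 higher and Tek and Plvap lower. In all, 2988 genes were higher and 3975 lower of 15347. After quantile normalization the balance turned, with 3614 higher and 3030 lower, and with a mean of at least 5 FPKM required 2391 were higher and 2375 lower. The total of 6963 was 4000 without the pair block and 4548 to 6408 with 1 pair left out, the lowest without the day 11 Dppa2/4 pair.

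**Figure D4:**
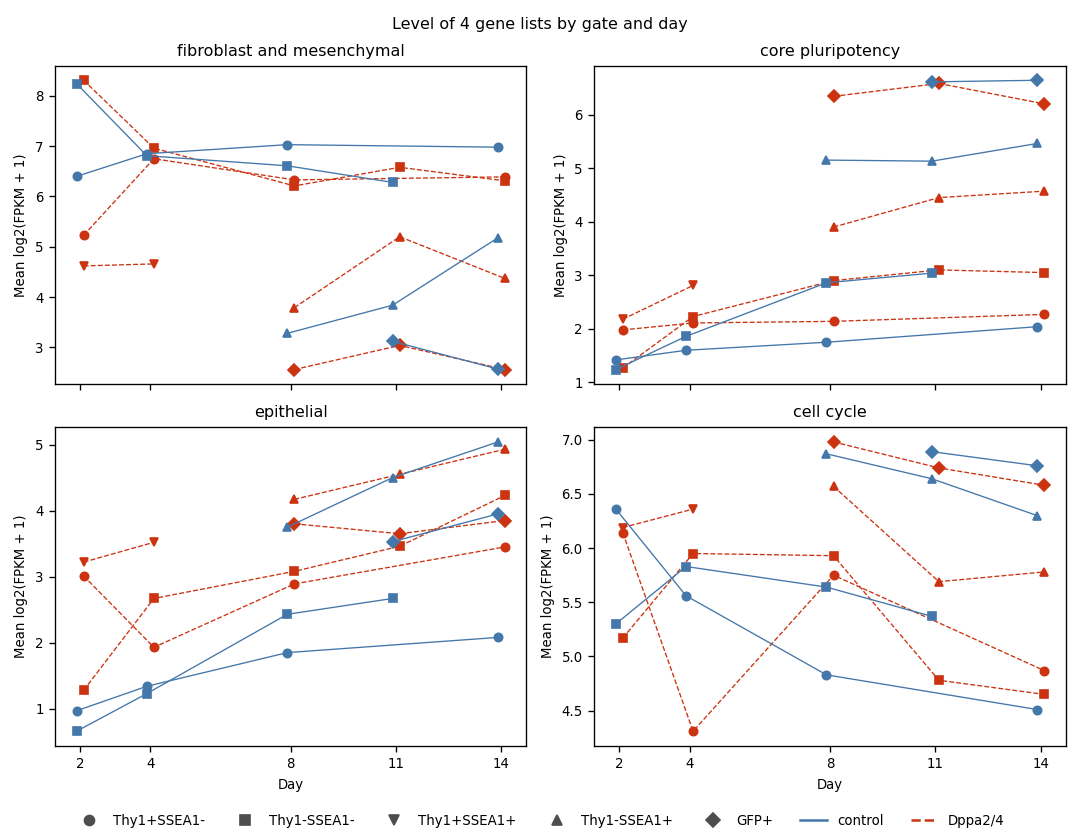
Mean log2(FPKM + 1) over the fibroblast, core pluripotency, epithelial and cell cycle lists by day, gate and arm. The pluripotency mean is 6.20 to 6.64 in GFP+ cells and 1.24 to 3.10 in the SSEA1- gates, and the fibroblast mean is 2.56 to 3.12 and 5.23 to 8.31.

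Time within a gate was fitted across both arms. In Thy1-SSEA1- cells (9 libraries, days 2 to 14) 6 of the 415 calls passed again without day 2, though the slopes of the 409 still tested were a median of 0.89 of those with it and none changed sign. Spink3, a protease inhibitor, rose by 0.65 per day on the log2 scale (SE 0.13, adjusted p = 0.0405), Dppa5a by 0.58 (SE 0.03, adjusted p = 0.000186), Tdgf1 by 0.50 (SE 0.05, adjusted p = 0.00381), Krt18, a keratin of simple epithelia, by 0.41 (SE 0.04, adjusted p = 0.00441) and Epcam by 0.40 (SE 0.06, adjusted p = 0.0154). Col1a1 fell by 0.34 per day (SE 0.06, adjusted p = 0.0208) and Isg15 by 0.18 (SE 0.04, adjusted p = 0.0363). Of 22 epithelial genes 15 rose (20 adjusted over the list alone, camera adjusted p = 1.1e-22, and adjusted p = 0.089 with an estimated correlation). Of 29 core pluripotency genes 10 rose (17 adjusted over the list alone, camera adjusted p = 1.6e-14, and adjusted p = 0.11 with an estimated correlation). Of 33 fibroblast genes 9 fell (20 adjusted over the list alone, camera adjusted p = 6.8e-13, and adjusted p = 0.4 with an estimated correlation). Tfap2c and Rhox6 rose among 5 trophoblast genes (4 adjusted over the list alone, camera adjusted p = 0.00075, and adjusted p = 0.11 with an estimated correlation). Camera also placed germline (adjusted p = 0.00012) and endothelial genes (0.034) up and imprinted (0.0047) and cell cycle genes (0.0063) down, with an adjusted p from 0.4 to 0.76 with an estimated correlation. In all 252 genes rose and 163 fell of 14995. The count of 415 was 7 without day 2, 26 without the day 2 Dppa2/4 library, 35 without the day 11 control library, 121 without the day 2 control library, 191 without the day 8 control library, and 221 and 240 without the day 4 and day 14 Dppa2/4 libraries. The count was 228 without a filter on low values, 718 among protein-coding genes alone and 219 with a mean of at least 5 FPKM, of which 110 rose and 109 fell.

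In Thy1+SSEA1- cells, which kept the fibroblast antigen (8 libraries), Adm, which encodes adrenomedullin, rose by 0.33 per day (SE 0.05, adjusted p = 0.049), Krt18 by 0.26 (SE 0.04, adjusted p = 0.049), Tdgf1 by 0.21 (SE 0.04, adjusted p = 0.0496) and Ier3 by 0.21 (SE 0.03, adjusted p = 0.049). Nop56, a protein of ribosome assembly, fell by 0.23 (SE 0.03, adjusted p = 0.049) and Sfpq, a splicing factor, by 0.22 (SE 0.03, adjusted p = 0.049). Krt18 and Crb3 were the risers among 20 epithelial genes (4 adjusted over the list alone, camera adjusted p = 0.00032). Ier3 rose among 18 stress genes (8 adjusted over the list alone, camera adjusted p = 1.6e-05), and Parp1 fell among 24 DNA damage genes (5 adjusted over the list alone, camera adjusted p = 5.8e-06). Camera also placed cell cycle (adjusted p = 5.8e-07) and chromatin genes (1.6e-05) down and immune genes up (0.019), and each of these 6 lists had an adjusted p = 0.8 with an estimated correlation. In all 192 genes rose and 118 fell of 14742. After quantile normalization the balance turned, with 93 up and 127 down. The count of 310 was 2769 (1686 up and 1083 down) without the library labelled Dppa2/4 day 4 Thy1+SSEA1-. It was 0 without any 1 of the 4 control libraries or of the day 8 and 14 Dppa2/4 libraries, and without the day 2 Dppa2/4 library Snora62 and Atp1b1 passed. Limma also called 0 without a filter on low values (4511 at an unadjusted p under 0.05) and without the variance trend (3728).

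The pair of day 2 libraries titled rtTA-MEF was read as 1 against 1, by size of change alone. Dppa4 was 5270 FPKM in the Dppa2/4 library and 1.42 in the control, and Dppa2 4440 and 1.53. The other 8 of the 10 largest rises and the 10 largest falls were short RNAs, from AL646020.1 (3620 FPKM, listed at 0 in the control) to mmu-mir-703 (48400 FPKM in the control). Epithelial genes were higher by a median of 2.80 (17 of 18 genes, above 100% of 10000 random lists of matched level), with the protease inhibitor Spint1 at 46.9 against 0.328 FPKM and Ocln at 6.57 against 0.0977. Endothelial genes were higher by a median of 2.23 (6 genes, percentile 99.9), keratinocyte genes by 1.48 (5 genes, 98.3) and trophoblast genes by 1.63 (4 genes, 97.8). Neural genes were higher by 1.28 (6 genes, 98.6) and pluripotency genes by 1.02 (18 genes, 97.4). Interferon genes were higher by 0.76 (94.8) and germline genes by 0.87 (72.0), and fibroblast genes were lower by a median of -0.24 (6.3). Taf7l stood at 11.9 against 0.0329 FPKM and Isg15 at 95.2 against 36.7. In all 586 of 14420 genes were at least 4-fold higher and 143 lower, on a median difference of 0.28 over all genes. Pou5f1 was 122 FPKM in the control and 1120 in the Dppa2/4 library, against 75.7 to 522 in the OSKM libraries of day 2, so these libraries cannot be taken as cells without OSKM. The differences within this pair cannot be told apart from that difference in Pou5f1.

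Against those 2 libraries, the day 2 OSKM libraries (n = 4) differed in 7 short RNAs of 14501 genes (543 at an unadjusted p under 0.05), 5 higher and 2 lower. Snord49a (549 FPKM), AC161253.2 (266), Snord7 (47.1) and AC105256.1 (28.6) were listed at 0 in the rtTA-MEF libraries. SNORD18 and SNORA42 were listed at 0 in the OSKM cells. The rtTA-MEF libraries name no gate, were less deep and may hold OSKM, so this contrast is not one of OSKM alone. Cell cycle (camera adjusted p = 1.6e-06) and interferon genes (1.7e-05) were lower in the sorted OSKM libraries. Adjusted over the list alone, 0 of 28 and 2 of 18 genes passed, and with an estimated correlation the camera adjusted p was 0.97. A change of 2 on the log2 scale was recovered in 0% of simulated genes at this size. Of the 7, SNORD18, Snord7 and AC161253.2 passed without a filter on low values.

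Of the 4 Dppa2/4 libraries without a matched control, the Thy1+SSEA1+ libraries of days 2 and 4 entered no comparison and were read by gene. The genes named are those of the lists with the largest rise over the highest control library of the day, of any gate. No control library of this gate exists, so arm and gate cannot be told apart in these values. Dppa2 in the Thy1+SSEA1+ libraries was 612 FPKM on day 2 and 92.4 on day 4. On day 2 these cells had Tex19.1 at 59.6 FPKM, where the highest control library of that day had 0.404, Spint1 at 63.5 (0.763), Cldn6, a claudin of embryonic epithelia, at 24.2 (0.0684) and Taf7l at 21.4 (0.135). On day 4 they had Cldn6 at 30.1 (0.0854), Tex19.1 at 42.1 (0.591), Lefty2 at 29.7 (0.163) and Cldn4 at 37.3 (0.6).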

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

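The test of library depth and the splits of the samples were planned, and the other tests of this part were chosen after the result was seen.

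The library labelled Dppa2/4 day 4 Thy1+SSEA1- had Dppa2 and Dppa4 at control level. Over the 4214 genes called from the other 12 strata, a choice that favours those strata, the difference of its stratum was 0.104 of their mean, and 54.9% of the genes went in the called direction, against 82.0 to 97.1% in the others, values that a library of control cells would give. A swap with its control partner is argued against, since the control day 4 Thy1+SSEA1- library had 0.319 FPKM of Dppa2. Whether the cells came from the Dppa2/4 arm and did not express the construct stays open. The library correlated at 0.9415 with its partner and at most at 0.9564 with any other control library, that of day 8 Thy1+SSEA1- cells. Its cell cycle mean of 4.31 lay below that of control Thy1+SSEA1- cells, at 5.56 on day 4, 4.83 on day 8 and 4.51 on day 14. A mix-up with a library of another day was not tested and stays open too.

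Interferon response genes were higher with Dppa2/4, though by little in the GFP+ gate. Immune cells in the libraries are argued against, since the median rise over Ptprc, Tyrobp, Fcer1g, Lyz2, C1qa, C1qb and C1qc was -0.138 FPKM, with Lyz2 at -2.19. Of the other markers Cd68 (6.27), Laptm5 (2.28) and Cd14 (0.759) were higher and Cd52 (-0.965) lower, beside 30.1 for Isg15. Library depth is argued against too, since at equal depth the score difference was 1.06 (95% interval 0.64 to 1.47 over 13 strata). A response to the transduction itself, which was not tested, and the amount of Dppa2 stay open: over 11 strata outside the GFP+ gate, Pearson r was 0.78 (two-sided permutation p = 0.00501) and Spearman rho 0.56 (permutation p = 0.0763), and r was 0.44 (permutation p = 0.241) without day 4 Thy1+SSEA1- and day 11 Thy1-SSEA1+.

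Day 2 Thy1-SSEA1- cells had Xist, the RNA of the inactive X, at 58.4 FPKM in control and 45.1 with Dppa2/4, against 0.604 and 0.732 in Thy1+SSEA1- cells, with Col1a1 at 2430 and 2100 against 560 and 84.6 and Pou5f1 at 94.9 and 75.7 against 336 and 327. Mostly female cells are argued against, since the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had a median ratio of 1.23 between the gates. Fibroblasts without OSKM in the gate stay open, since the highest of the 4 ratios of Pou5f1 and Sox2 was 0.34, and a share of such cells would lower both. High Xist was not limited to day 2. Over all days of the Thy1-SSEA1- gate it was 2.48 to 58.4 FPKM in control and 5.28 to 45.1 with Dppa2/4. In Thy1+SSEA1- cells it reached at most 1.14 and 1.9, so leaving out day 2 does not remove this difference between the gates.

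No other split drawn called as many genes in the main comparison (3933 genes, at most 1562 in 99 other splits of 100). The same held for SSEA1+ or GFP+ against other gates (69 and 55, with 1 of 100 splits as large) and for Thy1-SSEA1- against Thy1+SSEA1- (4 and 0 over 64 splits). The splits treat each stratum or pair as independent, and the labels give no independent transductions. A difference between the cultures of the arms is therefore not excluded by them. For late against early days 2 of 100 splits, the real one included, gave as many genes. The other of these gave 13 against 4, so the count does not set the real grouping apart, and the reason was not tested further. The splits are too few for a share under 0.05 in Thy1-SSEA1+ against Thy1+SSEA1- (1 of 8 splits as large, 3656 genes, at most 1 in the others) and GFP+ against Thy1-SSEA1+ (1 of 16, 6963 genes, at most 2).

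The signed effect of Dppa2/4 was higher in days 8 to 14 than in days 2 and 4 for Crabp2 (1.70), Neil3 (1.33) and Dzip3 (0.99). It was lower for Agpat2 (-1.18). That contrast mixes time with gate. None of the 4 genes passed without the stratum block or without the library labelled Dppa2/4 day 4 Thy1+SSEA1-. In SSEA1+ or GFP+ strata the effect was lower than in the other gates for Dppa4 (-5.11), Dppa2 (-4.97), Apoc1 (-3.41), Ly6g6c (-2.68), Amt (-2.44), Stmn2 (-2.24), Des (-2.13), Tubb3 (-2.09), Cldn6 (-2.03), Ocln (-1.61) and Eras (-1.39). It was higher there for Wnt16 (2.54), Abat (2.48), Gdpd2 (2.42), Fbxo32 (2.11), Igfbp3 (1.90) and Btg2 (1.23), and of these genes Stmn2 passed without the day 11 GFP+ control library. The Dppa2/4 day 2 Thy1+SSEA1+ library, outside the comparisons, had Tex19.1 at 59.6 FPKM, Spint1 at 63.5 and Cldn6 at 24.2, where the other Dppa2/4 libraries of that day reached 48.0, 61.4 and 16.7. That of day 4 had Cldn6 at 30.1 FPKM, Tex19.1 at 42.1 and Lefty2 at 29.7, where the others reached 8.72, 17.5 and 9.24. The genes given for these Thy1+SSEA1+ libraries were picked for the largest rise over control libraries of the day.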

How the results depend on the processing

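The alternatives without the library labelled Dppa2/4 day 4 Thy1+SSEA1-, with protein-coding genes alone and, for the gates and the change per day, without day 2 were chosen after the result was seen. The values rest on 1 library per arm, day and gate, on deposited FPKM without counts, and on a log2 scale that compresses low genes. A count-based test and another alignment were not run. The cause of the shifts below was not tested.

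With no replicate block, that is without the term for stratum or pair, the main comparison called 719 genes higher (2629 with it) and 86 lower (1304), and 805 of the 3933 calls were shared. Late against early days and SSEA1+ or GFP+ against other gates called 0 (4 and 69, with 692 and 795 at an unadjusted limma p under 0.05). Thy1-SSEA1- against Thy1+SSEA1- called 15 (4), Thy1-SSEA1+ against Thy1+SSEA1- 1793 (3656) and GFP+ against Thy1-SSEA1+ 4000 (6963).

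In the main comparison, quantile normalization called 2107 lower, a mean of at least 5 FPKM 1257 higher, leaving out day 8 1516 and 662, day 11 1561 and 547, and day 14 482 lower. Single strata left out gave 2120 to 2722 higher and 852 (without day 11 Thy1-SSEA1-) to 1492 lower (without day 4 Thy1+SSEA1-). No shared gene changed sign in these settings. Without the day 4 Thy1+SSEA1- stratum, 3691 of 3931 calls were shared. Of 47 named genes, 23 lost their call with no replicate block, 14 without day 8, 14 without day 14, 12 without day 11, 8 without a filter and 3 after quantile normalization. List scores past the threshold numbered 5 to 8 with 1 stratum left out.

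Late against early days called 2 genes without the day 11 GFP+ control library (Neil3 and Dzip3) and 0 without the library labelled Dppa2/4 day 4 Thy1+SSEA1-. SSEA1+ or GFP+ against other gates called 140 at a pseudocount of 0.1, 13 without a filter, 44 at a mean of at least 5 FPKM, 263 with protein-coding genes alone, and 1 without the day 11 GFP+ control library (Stmn2).

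Thy1-SSEA1- against Thy1+SSEA1- called 21 at a pseudocount of 0.1, 0 without a filter, 8 at a mean of at least 5 FPKM, 8 after quantile normalization, 82 without day 2, 1 (Defb1) without the library labelled Dppa2/4 day 4 Thy1+SSEA1-, and with 1 pair left out 0 (without any of the 3 control pairs or the day 8 or 14 Dppa2/4 pair) to 7 (without the day 2 Dppa2/4 pair). Thy1-SSEA1+ against Thy1+SSEA1- called 0 without a filter and 1006 to 3365 with 1 pair left out, and GFP+ against Thy1-SSEA1+ 4548 to 6408.

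Change per day in Thy1+SSEA1- cells (310) gave 0 without a filter, 0 without the trend, 631 at a mean of at least 5 FPKM, 928 with protein-coding genes alone, and 0 to 2769 with 1 library left out, the latter without that labelled Dppa2/4 day 4. In Thy1-SSEA1- cells (415) it gave 228 without a filter, 219 at a mean of at least 5 FPKM, 718 with protein-coding genes alone, 7 without day 2, and 26 to 330 with 1 library left out. OSKM against rtTA-MEF (7) gave 3 without a filter, 0 with protein-coding genes alone, a setting that tests none of the 7 short RNAs, and 0 to 13 with 1 library left out. The 1 against 1 pair kept its counts within 1.5 times at the other settings.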

Other observations

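The tests of this part were chosen after the result was seen, and the families of gene symbols were formed for it. The hypergeometric test treats the genes of a family as independent. Correlation between them was not estimated, so its adjusted p-values can be far too small. Of 83 genes named Rpl, after proteins of the large ribosomal subunit, 28 fell with Dppa2/4, 0 rose and 55 did not pass. Their median was -0.25 (limma calls, hypergeometric adjusted p = 2.8e-09 over 152 families). After quantile normalization 26 fell (adjusted p = 0.00082), and without the day 4 Thy1+SSEA1- stratum 31 of 82 (adjusted p = 2.5e-10). Of 59 genes named Rps, 20 fell and 2 rose, with a median of -0.23 (adjusted p = 1.2e-06), but after quantile normalization 13 fell (adjusted p = 0.38), so that enrichment was lost. Families were formed from the symbol alone, with no filter on gene type, so pseudogenes named Rpl or Rps can be counted as members. Some of these symbols belong to genes with pseudogenes of like sequence. Claudin genes were higher in 9 of 13, with 1 lower and a median of 0.76 (adjusted p = 0.0016, and 0.02 after quantile normalization). Phosphodiesterase genes named Pde were higher in 11 of 22, with a median of 0.27 (adjusted p = 0.007, and 0.025 after quantile normalization). Ifi genes, which the interferon list holds in part, were higher in 10 of 11 (adjusted p = 8.1e-06). Genes named Srsf (6 of 12 lower), Polr (9 of 28) and Wdr (14 of 61, with 6 higher) had an adjusted p = 0.007 each, and Hdac (5 of 12 lower) 0.047. Of these 4, Wdr passed after quantile normalization (adjusted p = 0.02).

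Day 2 Thy1-SSEA1- cells also had H19, an imprinted growth-restraining RNA, at 2860 FPKM in control and 3240 with Dppa2/4, against 231 and 87.6 in Thy1+SSEA1- cells, and Sox2 at 2.54 and 1.61 against 7.45 and 12.2. In Thy1-SSEA1+ cells some pluripotency genes, chosen after values were seen, stood higher in control than with Dppa2/4: Pou5f1 was 860 ± 63.5 FPKM (SD, 3 days) against 373 ± 102, Sox2 68.4 ± 6.83 against 23.9 ± 11.4 and Tdgf1 293 ± 41.1 against 154 ± 85.1. Tex19.1 went the other way, at 10.7 ± 7.61 against 40 ± 9.34. The difference of the effect on Pou5f1 between gates is not read here, since Pou5f1 drives the sorted reporter.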
